A study of Mus musculus with 64 samples.

How the data were processed

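Gene expression was measured by bulk 3' mRNA sequencing of cultured mouse natural killer (NK) cells. NK cells are lymphocytes that kill infected or transformed cells and secrete cytokines. Per the labels' protocols, spleen NK cells were grown for 5 days with low-dose IL-2 and IL-15 bound to its receptor alpha chain. They were then exposed for 5 hours to nothing, to prostaglandin E2 (PGE2, 100 ng/ml) or to medium conditioned by BRAF-mutant tumour cells that produce PGE2. In the stimulated arm, 1 hour of this treatment was followed by 4 hours on antibody against NK1.1, an activating receptor whose crosslinking mimics target recognition. Cells came from wild-type (WT) mice, from mice lacking the PGE2 receptor EP2 (gene Ptger2; here EP2KO), and from mice lacking EP2 in which Cre expressed from the Gzmb locus deletes the receptor EP4 (gene Ptger4; here DKO).

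The authors deposited 1 table of raw counts with 36273 gene symbols and 64 libraries, which fall into 18 groups. Per the labels' protocols, libraries carried sample barcodes and unique molecular identifiers. Whether the deposited counts are molecules or reads, and the aligner, counting tool and annotation release, are not given in the sources used here. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and DESeq2 was used. All values in the table were whole numbers, every column matched 1 sample, and 0 rows named no gene. Gene positions, where given, are from GENCODE M21 for GRCm38, in which 35067 of the symbols matched 1 gene. Because counting by strand is not stated for the deposited table, counts of antisense or overlapping genes may be shared with their neighbours, and near-identical copies are uncertain.

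Library totals ranged from 753973 to 1693750 counts, with a median of 1256163. Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 10723 genes holding 99.21% of all counts. At these totals, 1 count in a library is close to 1 CPM (counts scaled to a library total of 1000000), so genes of a few CPM rest on a few counts per library. Simulated counts with the means, spreads and library sizes of the real data were used to check the tests. For PGE2 in unstimulated WT, with 2 treated libraries, edgeR recovered 16.4% of the genes changed by 1.5-fold, 44.8% of those changed by 2-fold and 78.8% of those changed by 4-fold, and made 8 false calls. For PGE2 in unstimulated DKO, the same shares were 16.4%, 43.3% and 81.8%, with 2 false calls. For the EP2KO minus WT difference of the PGE2 effect in stimulated cells, they were 7.46%, 35.8% and 78.8%.

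Counts were normalised by edgeR's trimmed mean of M values. All 64 libraries were fitted together with 1 mean per group by edgeR's quasi-likelihood method with robust dispersion estimation (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Each comparison is a contrast of group means. P-values were adjusted by the Benjamini-Hochberg method over the 10723 genes, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values with the standard error (SE) of the fit. The comparisons are anti-NK1.1 against no stimulation within each genotype, PGE2 or conditioned medium against untreated within each genotype and state, conditioned medium against PGE2 in WT, the interaction of each treatment with stimulation in WT, the interaction of each treatment with genotype (EP2KO minus WT and DKO minus EP2KO), and the untreated genotypes.

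A set of 25 gene lists, the comparisons, the tests and the rule for naming genes was fixed before the data were examined. The lists cover cAMP-PKA-CREB targets, NK cytokines and chemokines, cytotoxicity, NK activating receptors and adaptors, inhibitory receptors, cytokine receptors, NK transcription factors, trafficking and adhesion, immediate early and NF-kB/NFAT targets, IL-2/IL-15-STAT5 targets, interferon-stimulated genes, glycolysis and nutrient transport, ribosome biogenesis, cell cycle, heat shock and integrated stress response, the prostanoid pathway, oxidative phosphorylation, cholesterol synthesis, sex-linked genes, and markers of B cells, T cells, macrophages and dendritic cells, neutrophils, erythroid cells and melanoma cells. Lists with at least 5 tested genes were compared with all other genes by limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists and the 15 comparisons within a genotype, and again with an estimated correlation.

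Named genes are, for the comparisons within WT, the 10 with the largest rise and the 10 with the largest fall among called genes with an average log2 CPM of at least 4 and no overlap between the libraries of the groups. For the interactions, genotype comparisons and knockouts, 5 each way were taken by the same rule, without the overlap condition for interactions. Predicted genes and antigen receptor segments were passed over. To these were added up to 4 called members of each list with the smallest p, and always Ptger2, Ptger4, Ifng, Ccl5, Xcl1, Gzmb, Prf1, Crem and Nr4a1. Values of a gene named in WT may be given for the knockouts. Some genes that this rule takes are not reported here.

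A PGE2 signature score was the mean over the genes called for PGE2 in WT of their log2 CPM (prior count 2), with the sign turned for genes that fell, relative to the mean of the untreated libraries of the same genotype and state. In the results it is given for EP2KO and DKO libraries. For the closing comparison with WT, the WT libraries were scored too, with these genes, which were chosen on them, and with genes called for PGE2 in EP2KO, which were chosen on EP2KO libraries. An activation score was built in the same way from the genes called for anti-NK1.1, taken from EP2KO for WT and from WT for EP2KO and DKO, so that no library's activation score rests on genes chosen on itself. Scores were compared by two-sided exact permutation tests, with Benjamini-Hochberg values over the 14 score comparisons. The labels do not say what a replicate number marks, so the numbers were taken to pair the samples of a comparison only where it had at least 3 same-numbered pairs and the deviations of every pair from the group means correlated above 0.1. This held for 8 of the 27 comparisons with shared numbers (lowest r 0.101): anti-NK1.1 in DKO, PGE2 without stimulation in EP2KO and DKO, PGE2 with stimulation in WT and DKO, conditioned medium with stimulation in DKO, and both differences between genotypes in the effect of PGE2 without stimulation. Correlated effects that share untreated libraries were set against 20 simulations of unchanged groups. The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, the replicate number as a block, and leaving out each library in turn. Permutation tests and plots used R, Python 3.11.15 and matplotlib 3.10.9. No library was left out, and libraries of the same group were compared in 85 pairs for possible duplicates by a chi-square statistic per degree of freedom over genes with at least 20 counts in the pair, which ranged from 1.46 to 19.4. This statistic covers counting error only, so if the counts are reads, values above 1 do not rule out repeated libraries of 1 sample.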

Results

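Spleen NK cells of 3 mouse genotypes were profiled in 64 libraries. WT and EP2KO cells gave 4 libraries for each of 6 conditions and DKO cells gave 3, except that WT cells given PGE2 without stimulation gave 2 (replicates 2 and 4). The design asks how PGE2, alone or in medium conditioned by PGE2-producing tumour cells, alters resting and receptor-stimulated NK cells. It also asks which of these responses depend on the PGE2 receptors EP2 and EP4, which both signal by raising cyclic AMP (cAMP). Group means of the library totals ran from 933830 ± 113600 counts (SD, n = 4) in unstimulated WT cells with conditioned medium to 1567300 ± 110800 (n = 3) in stimulated untreated DKO cells. Unstimulated libraries with conditioned medium were shallower in each genotype, at 933830, 1013000 and 1185200 counts in WT, EP2KO and DKO, against 1197300, 1171300 and 1313000 without treatment. The labels do not say whether replicates are separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Fold changes below are log2 values ± SE from edgeR's quasi-likelihood fit, and adjusted p-values are its Benjamini-Hochberg values.

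The targeted genes were measured first. Ptger2, which encodes EP2, lies on chromosome 14 from 44988195 to 45003820 (GRCm38) and was lowly expressed in every genotype. Without stimulation or treatment it stood at 5.00 ± 1.80 CPM in WT (SD, n = 4), 3.72 ± 1.31 in EP2KO (n = 4, exact permutation p = 0.257, adjusted over 8 such tests 0.411) and 2.90 ± 0.65 in DKO (n = 3). After stimulation it stood at 25.2 ± 9.48 CPM in WT and 9.67 ± 3.45 in EP2KO (exact permutation p = 0.0286, the smallest this design allows, adjusted 0.114). Per library it ranged from 3.32 to 36.6 CPM in WT, 2.41 to 13.9 in EP2KO and 2.14 to 14.9 in DKO. Ptger4, which encodes EP4, lies on chromosome 15 from 5206661 to 5244187 and ranged from 9.58 to 81.3 CPM in WT, 14.2 to 68.3 in EP2KO and 31.3 to 125.1 in DKO. Its mean in untreated unstimulated cells was 22.7 ± 6.29, 29.5 ± 2.48 and 41.1 ± 5.41 CPM in WT, EP2KO and DKO, and DKO lay above EP2KO (exact permutation p = 0.0286, adjusted 0.114). The sources used here do not place the deleted parts of the genes. A 3' tag can lie outside them, so these levels check neither label.

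Markers of other cell types stayed low. The B cell, T cell, macrophage and dendritic cell, neutrophil, erythroid and melanoma lists each took under 0.1% of the counts in every group. Of the B cell list only Ighm was tested, at a mean of 60.5 CPM, and no melanoma gene was abundant enough to test, the highest mean being 1.91 CPM for Mitf. Mitochondrial genes took a mean of 8.15% to 11.6% of counts by group. Without stimulation this share was higher with treatment: 8.93% ± 1.25 (SD, n = 4) untreated, 10.8% ± 0.427 (n = 2) with PGE2 and 11.1% ± 1.25 (n = 4) with conditioned medium in WT, 10.2%, 11.3% and 11.6% in EP2KO, and 8.78%, 9.03% and 9.41% in DKO. The 20 most abundant genes took 19.4%, 21.7% and 22.7% of the counts in the same 3 WT groups, and T cell markers took 0.0413% ± 0.0021, 0.0324% ± 0.000352 and 0.0283% ± 0.00255 (SD). B cell markers took 0.00845% ± 0.00119, 0.00404% ± 0.00113 and 0.00496% ± 0.000693, with every treated library below every untreated one, and neutrophil markers 0.0102% ± 0.0113, 0.0199% ± 0.0217 and 0.0133% ± 0.0114. None of these shares was tested. Sex-linked genes separated the genotypes: Xist, expressed from the inactive X chromosome, averaged 669.1 CPM in the 46 WT and EP2KO libraries and 42.0 ± 11.4 CPM (SD) in the 18 DKO libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were high in DKO. Each of these 5 genes was also counted in libraries of the other sex, at 6.86% to 13.3% of its mean over all 64 libraries. DKO cells therefore differ from the others in sex as well as in genotype, and every statement about DKO below carries that limit.

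In untreated unstimulated cells the genotypes differed at few genes. Between EP2KO and WT (n = 4 and 4), 4 genes were higher and 3 lower at an adjusted p under 0.05. Wdfy1, on chromosome 1 from 79702262 to 79776143, rose by 1.66 ± 0.19 in EP2KO. Rpgrip1, on chromosome 14 from 52110704 to 52163546 and 7.11 Mb from Ptger2, stood at 9.21 CPM in EP2KO against 37.5 in WT. Without the untreated WT replicate 4 the count was 4. Between DKO and EP2KO (n = 3 and 4), 4 genes rose and 2 fell, and all 6 are sex-linked: Eif2s3y (4.36 ± 0.26), Ddx3y (3.82 ± 0.35), Kdm5d (5.77 ± 0.49) and Uty (5.31 ± 0.49) rose, and Xist (−3.62 ± 0.19) and its antisense gene Tsix (−2.13 ± 0.34) fell. Tsix overlaps Xist and its counts may be reads of Xist. Without the EP2KO replicate 3 the count was 10. Neutrophil markers were higher in EP2KO than in WT when adjusted over the list alone (4 of 6) and lower in DKO than in EP2KO (6 of 6), with none called over all genes. One of them, S100a8, also varied between replicate numbers. Over all conditions its means per number ran from 12.3 to 95.1 CPM in WT, 28.6 to 240.7 in EP2KO and 9.42 to 34.9 in DKO.

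Crosslinking NK1.1 changed the WT transcriptome widely, with 2465 genes higher and 2043 lower after 4 hours (n = 4 and 4). Among the largest rises were Il2, the T cell growth factor (3.58 ± 0.42, from 4.57 to 55.8 CPM), Csf2, which encodes GM-CSF (3.42 ± 0.32, from 9.82 to 106 CPM), the transcription factors Atf3 (3.35 ± 0.33) and Egr2 (3.18 ± 0.16), the precursor of microRNA-155, Mir155hg (3.28 ± 0.23), and Zc3h12c (3.61 ± 0.35). Ifng, which encodes interferon-gamma and lies on chromosome 10 from 118441046 to 118445892, rose by 3.12 ± 0.20, from 217 to 1888 CPM. Among the largest falls were the interferon-gamma receptor gene Ifngr1 (−2.34 ± 0.15, from 1160 to 228 CPM), the chemokine receptor gene Cxcr3 (−2.29 ± 0.26), the G protein gene Gna15 (−2.44 ± 0.26), Rnf125 (−2.38 ± 0.18) and Fam189b (−2.38 ± 0.24). The receptor genes Ptger2 and Ptger4 themselves rose, by 2.28 ± 0.30 and 1.47 ± 0.20.

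The list of NK cytokines and chemokines rose as a group in WT: 14 of 19 tested members were higher, 1 was lower and 4 were not called, the same as adjusted over the list alone (camera adjusted p = 1.44e-13). Xcl1, a chemokine for dendritic cells, rose by 2.40 ± 0.17. All 20 ribosome biogenesis genes rose, among them Gnl3 (2.06 ± 0.14) and Nop58 (2.02 ± 0.14; camera adjusted p = 1.44e-29), and all 20 were called over the list alone. Of 24 immediate early and NF-kB/NFAT targets, 21 rose and none fell (21 over the list alone; camera adjusted p = 5.44e-26), with Rel at 2.85 ± 0.14 and Nr4a1 at 2.18 ± 0.21. Heat shock and integrated stress response genes rose (15 of 19, 1 lower; 15 and 1 over the list alone; camera adjusted p = 1.20e-08), led by Hspa5 (2.26 ± 0.14) and Atf4 (1.52 ± 0.11). IL-2/IL-15-STAT5 targets rose in 9 of 20 and fell in 4 (9 and 4 over the list alone; camera adjusted p = 2.57e-04), with Il2ra at 2.94 ± 0.20 and Pim1 at 2.28 ± 0.12. Of the cAMP-PKA-CREB targets, 12 of 24 rose and 3 fell (12 and 3 over the list alone; camera adjusted p = 1.54e-04, adjusted p = 0.0801 with an estimated correlation), while Crem itself was not called (−0.17 ± 0.20).

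Most other lists moved in both directions in WT. Of 21 cytotoxicity genes, 9 rose and 5 fell (9 and 6 over the list alone; camera adjusted p = 0.579), with the perforin gene Prf1 at 1.63 ± 0.18 and the granzyme gene Gzmb at 0.68 ± 0.23. Of 20 NK activating receptors and adaptors, 5 rose and 12 fell (5 and 13 over the list alone; camera adjusted p = 0.291). Crtam rose by 3.05 ± 0.16, while Klrb1c, which encodes NK1.1, and the Fc receptor gene Fcgr3 changed by −1.18 ± 0.13 and −2.24 ± 0.26. Trafficking and adhesion genes fell in 11 of 19 (2 rose; camera adjusted p = 0.0486, adjusted p = 0.2 with an estimated correlation). Cell cycle genes fell in 10 of 28, among them Birc5 (−1.38 ± 0.32; camera adjusted p = 0.00728, adjusted p = 0.708 with an estimated correlation). Glycolysis and nutrient transport genes rose in 7 of 18 and fell in 3 (camera adjusted p = 0.0562), with Hk2 at 2.12 ± 0.26 and Slc7a5 at 2.06 ± 0.23. The counts higher and lower were 6 and 8 of 20 cytokine receptors, 5 and 4 of 15 inhibitory receptors, 4 and 6 of 18 NK transcription factors, 3 and 5 of 21 interferon-stimulated genes, 2 and 4 of 21 oxidative phosphorylation genes, 4 and 4 of 18 cholesterol synthesis genes and 5 and 0 of 10 prostanoid genes, and camera called none of these lists. Of the markers, 1 T cell gene rose and 2 fell, 2 macrophage and dendritic cell genes fell, Ighm fell by 0.71 ± 0.18, and no neutrophil or erythroid gene was called. Of the sex-linked genes, Xist rose by 0.40 ± 0.14.

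The knockouts responded to anti-NK1.1 with 1969 genes higher and 1606 lower in EP2KO (n = 4 and 4) and 1761 higher and 1481 lower in DKO (n = 3 and 3). Ifng rose by 3.07 ± 0.20 and 3.10 ± 0.23, Prf1 by 1.56 ± 0.18 and 1.63 ± 0.21 and Gzmb by 0.84 ± 0.23 and 0.81 ± 0.26 in EP2KO and DKO. All 20 ribosome biogenesis genes rose in both, and of the NK cytokines and chemokines 13 rose in each. Across the 22 lists and 15 comparisons within a genotype, camera called 100 of 330 pairs, 41 up and 59 down, and 56 pairs (26 up and 30 down) with an estimated correlation.

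PGE2 without stimulation changed 318 genes in WT cells, 205 higher and 113 lower (n = 2 treated and 4 untreated). The cAMP-responsive repressor gene Crem, on chromosome 18 from 3266048 to 3337748, rose by 2.23 ± 0.21, from 87.8 to 413 CPM (adjusted p = 5.89e-12). Large rises were also seen for Bend4 (3.53 ± 0.44), Ier5l (2.83 ± 0.38), the angiogenic factor gene Vegfa (2.56 ± 0.28), the triglyceride synthesis gene Dgat1 (2.24 ± 0.23) and Stat3 (1.99 ± 0.15, from 180 to 717 CPM). Ncr1, which encodes the activating receptor NKp46 and lies on chromosome 7 from 4337724 to 4345164, fell from 276 to 85.8 CPM (−1.69 ± 0.21, adjusted p = 1.41e-08). Also lower were Il27ra (−2.42 ± 0.48), Asb2 (−2.21 ± 0.38), Chn2 (−2.18 ± 0.30), the phosphatase gene Ptpn6 (−1.88 ± 0.19), Myc (−1.58 ± 0.30) and the receptor genes Cd160 (−1.51 ± 0.33) and Cd244a (−1.50 ± 0.24). Without PGE2 replicate 2 the count was 129 and without PGE2 replicate 4 it was 174, each with 1 treated library that is assumed to vary like the other groups.

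By list, 10 of 24 cAMP-PKA-CREB targets rose and none fell (12 and 1 over the list alone; camera adjusted p = 9.93e-21), including the G protein signalling regulators Rgs2 (1.85 ± 0.17) and Rgs1 (1.62 ± 0.18). Of 20 NK activating receptors and adaptors, 1 rose and 4 fell, and 1 and 12 over the list alone (camera adjusted p = 2.00e-08). Slamf7 fell by 1.25 ± 0.23. Ribosome biogenesis genes fell in 5 of 20 (9 over the list alone; camera adjusted p = 1.17e-08), with Gnl3 at −0.85 ± 0.19. NK cytokines and chemokines fell in 2 of 19 (3 over the list alone; camera adjusted p = 0.0102, adjusted p = 0.480 with an estimated correlation), with Ltb, which encodes lymphotoxin beta, at −1.09 ± 0.21 and Flt3l at −1.39 ± 0.27. The major effector genes were not called: Ifng −0.22 ± 0.23, Prf1 −0.06 ± 0.22, Xcl1 −0.46 ± 0.21, Ccl5 −0.21 ± 0.25 and Gzmb −0.79 ± 0.29 (adjusted p = 0.145). Of 21 cytotoxicity genes 2 fell and none rose (4 and 1 over the list alone; camera adjusted p = 0.181), the death ligand gene Tnfsf10 (−1.19 ± 0.29) and Ctsw (−0.52 ± 0.14). NK transcription factors rose in 3 and fell in 1 of 18 (5 and 2 over the list alone), with Foxo1 at 0.93 ± 0.17, Ikzf2 at 1.37 ± 0.26 and Id2 at −0.81 ± 0.15. The chemokine receptor gene Cxcr4 rose by 1.44 ± 0.31 and the inhibitory receptor gene Tigit by 1.81 ± 0.51.

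Conditioned medium without stimulation changed 883 genes in WT, 488 higher and 395 lower (n = 4 and 4). Among the leading genes, Bend4 (3.06 ± 0.41), Ier5l (2.96 ± 0.34), Vegfa (2.48 ± 0.25), the AP-1 gene Fosl2 (2.01 ± 0.20), Crem (1.98 ± 0.19) and Stat3 (1.93 ± 0.13) rose. Serpina3f (−2.59 ± 0.48), Ncr1 (−1.92 ± 0.17, from 276 to 73.2 CPM), the kinase gene Pim2 (−1.58 ± 0.20) and Ptpn6 (−1.59 ± 0.15) fell. Gzmb, on chromosome 14 from 56258838 to 56262260, fell from 2209 to 1012 CPM (−1.13 ± 0.23). Without untreated replicate 1 the count was 522 and without untreated replicate 4 it was 483. With replicates 2 and 4 of the conditioned medium alone, a choice made after seeing the data to match the number of PGE2 libraries, it was 328.

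Of 24 cAMP-PKA-CREB targets 11 rose and 1 fell (14 and 1 over the list alone; camera adjusted p = 2.70e-19). NK activating receptors and adaptors fell in 5 of 20 and rose in 1 (12 and 1 over the list alone; camera adjusted p = 3.13e-07), with Slamf7 at −1.35 ± 0.19 and Cd244a at −1.49 ± 0.19. Ribosome biogenesis genes fell in 12 of 20 (12 over the list alone; camera adjusted p = 9.11e-12), among them Dkc1 (−0.96 ± 0.14). Cytotoxicity genes fell in 3 of 21 and rose in 1 (3 and 1 over the list alone; camera adjusted p = 0.0786), with Nkg7, a granule membrane gene, at −0.59 ± 0.17. Camera also called 4 lists down whose calls were lost with an estimated correlation: NK cytokines and chemokines (3 of 19 lower; adjusted p = 0.00372 and 0.438), IL-2/IL-15-STAT5 targets (4 lower and 1 higher of 20; 0.0176 and 0.225), cholesterol synthesis (2 of 18 lower; 0.00687 and 0.166) and oxidative phosphorylation (1 of 21 lower; 0.00343 and 0.693), where the first value of each pair is the adjusted p with the preset and the second the adjusted p with the estimated correlation. The T cell adaptor gene Lat fell by 1.36 ± 0.37 and the dendritic cell marker Itgax by 0.74 ± 0.19.

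The effects of PGE2 and conditioned medium in unstimulated WT shared direction widely. Both called 278 genes in the same direction, 182 higher and 96 lower, against 9.33 and 4.16 for independent lists of those sizes, and none in opposite directions; 40 genes were called for PGE2 alone and 605 for conditioned medium alone. All 318 genes called for PGE2 had the same sign with conditioned medium. The figures for independent lists leave out that both comparisons share the untreated libraries. Across genes, which are not independent replicates, the fold changes correlated with r = 0.704, against a mean of 0.361 in 20 simulations of unchanged groups that share the untreated libraries. No gene was called for both there, which is no test of agreement because no effect was simulated. The covariance was 0.193 against 0.0637 simulated. With the untreated libraries split between the comparisons, r averaged 0.429 and 128 genes were called for both. A direct test of conditioned medium against PGE2 in unstimulated WT called 0 genes with edgeR (295 at an unadjusted p under 0.05) and 0 with DESeq2.

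In stimulated WT cells, PGE2 changed 1676 genes, 643 higher and 1033 lower (n = 4 and 4). Ifng dropped from 1888 ± 647 to 525 ± 17.3 CPM (SD; −1.85 ± 0.18, adjusted p = 3.85e-12), Il2 from 55.8 to 7.04 CPM (−2.95 ± 0.39), Csf2 from 106 to 21.1 CPM (−2.32 ± 0.28), Tnf from 156 to 33.8 CPM (−2.20 ± 0.22) and the chemokine gene Ccl1 from 6250 to 1160 CPM (−2.42 ± 0.21). The growth factor gene Pdgfa (−2.54 ± 0.17), Lta (−2.58 ± 0.38), Tnfsf8 (−2.27 ± 0.17), Tnfsf14 (−2.10 ± 0.19) and the activation marker Cd83 (−2.19 ± 0.29) also fell. Rising genes included Bend4 (3.91 ± 0.35), the cAMP phosphodiesterase gene Pde4d (2.54 ± 0.23), Dgat1 (2.49 ± 0.23), Rnf125 (2.42 ± 0.18) and Ifngr1, on chromosome 10 from 19591949 to 19610229 (2.16 ± 0.15, from 228 to 1020 CPM). Ptger4 and Ptger2 fell by 1.26 ± 0.20 and 1.69 ± 0.29.

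NK cytokines and chemokines fell in 14 of 19 with none higher (14 and 1 over the list alone; camera adjusted p = 1.16e-21), with Xcl1 at −1.27 ± 0.17, while Ccl5 was not called (−0.14 ± 0.20). Immediate early and NF-kB/NFAT targets fell in 19 of 24 and rose in 1 (21 and 1 over the list alone; camera adjusted p = 8.94e-23), among them Egr2 (−1.87 ± 0.15) and Rel (−1.29 ± 0.13), and Nr4a1 was not called (−0.49 ± 0.19) except with the replicate number as a block (−0.47, adjusted p = 0.0149 in edgeR). Ribosome biogenesis genes fell in 18 of 20 (19 over the list alone; camera adjusted p = 1.98e-16), with Wdr43 at −0.94 ± 0.14. Heat shock and integrated stress response genes fell in 8 of 19 and rose in 1 (13 and 1 over the list alone; camera adjusted p = 3.00e-06), with Hspa5 at −1.18 ± 0.13. IL-2/IL-15-STAT5 targets fell in 8 of 20 and rose in 1 (8 and 1 over the list alone; camera adjusted p = 5.40e-05), with Il2ra at −1.55 ± 0.19 and Ccnd2 at −1.25 ± 0.13. Cytotoxicity genes fell in 7 of 21 and rose in 1 (8 and 3 over the list alone; camera adjusted p = 0.0898): Gzmb changed by −1.09 ± 0.23, Prf1, on chromosome 10 from 61297833 to 61304680, by −0.96 ± 0.18, and Rab27a, needed for granule release, by −0.98 ± 0.15. cAMP-PKA-CREB targets rose in 9 of 24 and fell in 4 (11 and 6 over the list alone; camera adjusted p = 3.95e-06), with Crem at 1.91 ± 0.19, Rgs2 at 1.88 ± 0.15 and Pde4b at 1.32 ± 0.16.

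Surface receptor and transcription factor lists moved both ways. NK activating receptors and adaptors fell in 7 of 20 and rose in 2 (camera adjusted p = 0.0443, adjusted p = 0.474 with an estimated correlation), with Cd244a at −1.70 ± 0.19 and Crtam at −1.31 ± 0.15. Of 19 trafficking and adhesion genes, 6 rose and 3 fell (7 and 3 over the list alone; camera adjusted p = 0.135). The lymph node homing gene Ccr7 (2.87 ± 0.46) rose, as did Ccr2 (1.49 ± 0.15), and the retention molecule gene Cd69 fell by 1.69 ± 0.14. Of 18 NK transcription factors, 6 rose and 2 fell (8 and 5 over the list alone; camera adjusted p = 0.0314, adjusted p = 0.438 with an estimated correlation), with Tcf7 at 0.83 ± 0.15, Ikzf2 at 1.55 ± 0.22 and Tbx21, which encodes T-bet, at −1.10 ± 0.21. Cytokine receptors rose in 4 of 20 and fell in 2 (camera adjusted p = 0.0259, adjusted p = 0.184 with an estimated correlation), among them Il12rb2 (1.40 ± 0.17). Of 15 inhibitory receptors 3 rose and 4 fell, with Havcr2 at −1.55 ± 0.19, and the ectonucleotidase gene Nt5e rose by 1.86 ± 0.37. Glycolysis and nutrient transport genes fell in 5 of 18 and rose in 1 (camera adjusted p = 0.124), with Slc2a3 at −1.32 ± 0.20 and Slc7a5 at −1.21 ± 0.21.

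Conditioned medium in stimulated WT changed 1654 genes, 665 higher and 989 lower (n = 4 and 4). Ifng fell from 1888 to 678 CPM (−1.48 ± 0.18), and Il2 (−2.85 ± 0.38), Lta (−2.90 ± 0.38), Tnf (−2.39 ± 0.22), Pdgfa (−2.41 ± 0.17), Prf1 (−1.11 ± 0.18) and Gzmb (−1.04 ± 0.23) fell too. Bend4 (3.33 ± 0.36), Ier5l (2.82 ± 0.41), Pde4d (2.15 ± 0.24), Nt5e (2.52 ± 0.34) and Crem (1.59 ± 0.19) rose. NK cytokines and chemokines fell in 13 of 19 (15 over the list alone), immediate early and NF-kB/NFAT targets in 17 of 24 (19 over the list alone), all 20 ribosome biogenesis genes fell, and cAMP-PKA-CREB targets rose in 9 of 24 and fell in 3 (9 and 3 over the list alone). Camera called these 4 lists with adjusted p = 9.62e-19, 1.71e-18, 1.26e-22 and 6.82e-08 in that order. Cytotoxicity genes fell in 5 of 21 (9 fell and 2 rose over the list alone; camera adjusted p = 0.156). Cholesterol synthesis genes fell in 2 of 18, among them Insig1 (−1.36 ± 0.25).

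In stimulated WT both treatments called 1190 genes in the same direction, 462 higher and 728 lower, against 39.9 and 95.3 for independent lists, and none in opposite directions; 486 were called for PGE2 alone and 464 for conditioned medium alone. The figures for independent lists again leave out the shared untreated libraries. Of the 1676 genes called for PGE2, 1668 (99.5%) had the same sign with conditioned medium. The fold changes correlated across genes with r = 0.843, against 0.491 in the simulations, and their covariance was 0.261 against 0.0599. With split untreated libraries r averaged 0.473 and 592 genes were called for both. A direct test of conditioned medium against PGE2 in stimulated WT (n = 4 and 4) called 1 gene, Epb41l2, a cytoskeletal linker (0.89 ± 0.17, adjusted p = 0.0374), and 491 at an unadjusted p under 0.05, while DESeq2 called 0. Epb41l2 was named because it was the single call. That count became 0 without PGE2 replicate 1, 3 or 4 or without conditioned medium replicate 2, 3 or 4, and 3 without conditioned medium replicate 1. It was 24 with the replicate number as a block, which was not taken to pair these samples. Recovery of true differences was not simulated for this test in either state, so low counts do not show that the treatments act alike. Ifng was 0.37 ± 0.18 higher with conditioned medium and was not called.

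**Figure D1:**
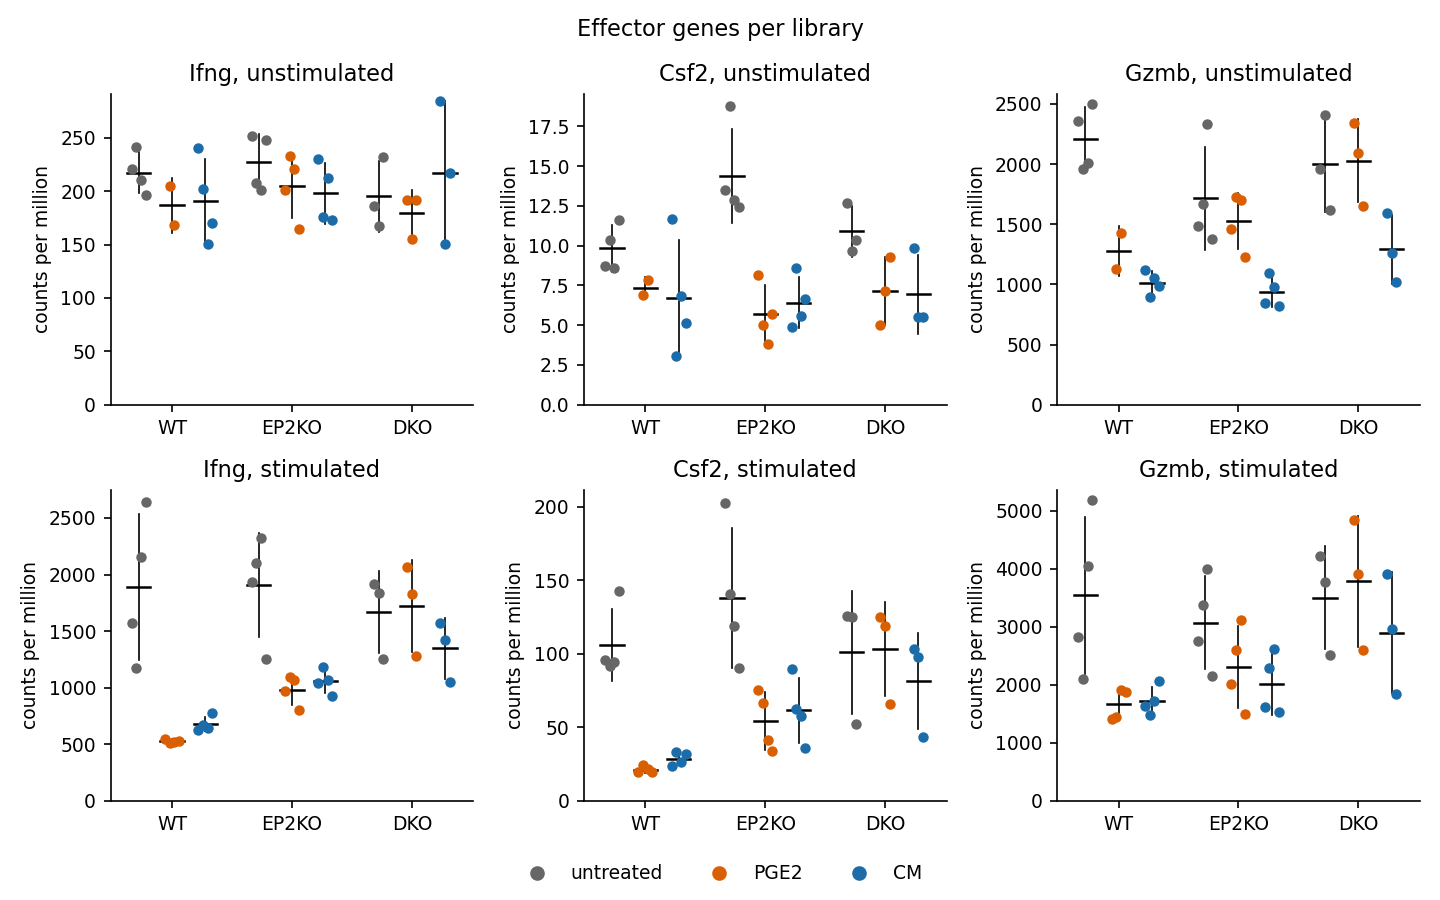
Each point is 1 library, with CPM of Ifng, Csf2 or Gzmb on the vertical axis and genotype on the horizontal axis, unstimulated in the upper and stimulated in the lower panels; horizontal lines are group means, vertical lines span 1 SD either way, and CM is conditioned medium. Stimulated WT cells averaged 1888 CPM of Ifng untreated and 525 with PGE2, while stimulated DKO cells averaged 1669 and 1724.

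The effects of the treatments depended on stimulation for part of these genes in WT. The PGE2 effect differed between stimulated and unstimulated cells at 140 genes, 49 more positive and 91 more negative after stimulation. It was more negative for Il2 (−3.26 ± 0.90), Ccl1 (−2.27 ± 0.31), Tnf (−1.95 ± 0.42) and Ifng (−1.63 ± 0.29, adjusted p = 3.83e-04), and more positive for Ifngr1 (1.50 ± 0.23) and Ncr1 (1.18 ± 0.26). Crem did not differ detectably (−0.32 ± 0.29). Of the NK cytokines and chemokines 6 were more negative and 1 more positive (11 and 1 over the list alone), and of the immediate early and NF-kB/NFAT targets 6 were more negative (13 over the list alone). Without unstimulated PGE2 replicate 2 the count was 33, and without replicate 4 it was 77. For conditioned medium the effect differed at 235 genes, 90 more positive and 145 more negative, among them Lta (−2.47 ± 0.63), Tnf (−1.99 ± 0.38), Jak2 (−1.82 ± 0.24), Ifngr1 (1.48 ± 0.20) and the chemokine receptor gene Cxcr6 (1.66 ± 0.39). Of the NK cytokines and chemokines 6 were more negative (9 over the list alone, with 1 more positive). That count was 144 without unstimulated untreated replicate 1, 136 without its replicate 4, 362 without stimulated untreated replicate 4, and 150 and 153 without stimulated conditioned medium replicates 1 and 4.

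EP2KO cells, which retain EP4, responded to PGE2 without stimulation at 338 genes, 188 higher and 150 lower, and to conditioned medium at 469, 239 higher and 230 lower (n = 4 and 4). With the replicate number as a block, PGE2 called 646 genes, and Xcl1 was called (−0.56, adjusted p = 0.00481) where it was not without the block (−0.55 ± 0.17, adjusted p = 0.0531). Crem rose by 2.17 ± 0.19 with PGE2 and 2.06 ± 0.19 with conditioned medium, and Fosl2 by 2.02 ± 0.20 and 2.10 ± 0.21. Ncr1 changed by −1.18 ± 0.16 and −1.40 ± 0.16, and Ptger4 by −0.81 ± 0.23 and −0.81 ± 0.24. The activation gene Egr3 changed by −1.79 ± 0.24 and −2.22 ± 0.27, and Gzmb fell with conditioned medium (−0.88 ± 0.23). cAMP-PKA-CREB targets rose in 11 of 24 with PGE2 (14 over the list alone) and in 10 with conditioned medium, where 1 fell (14 and 1 over the list alone). NK activating receptors and adaptors fell in 5 and 6 of 20 and rose in 1 each (7 and 1 over the list alone in both), and ribosome biogenesis genes fell in 10 and 14 of 20 (16 and 18 over the list alone). Camera called each of these lists for both treatments, also with an estimated correlation. Without PGE2 replicate 3 the PGE2 count was 222, and without conditioned medium replicate 3 the other count was 304.

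Stimulated EP2KO cells responded to PGE2 at 782 genes, 364 higher and 418 lower, and to conditioned medium at 1117, 483 higher and 634 lower (n = 4 and 4). Ifng fell by 0.96 ± 0.18 (from 1904 to 981 CPM) with PGE2 and by 0.85 ± 0.18 (to 1055 CPM) with conditioned medium. Il2 changed by −2.16 ± 0.34 and −2.03 ± 0.34, Tnf by −2.03 ± 0.21 and −2.00 ± 0.21, and Prf1 by −0.61 ± 0.18 and −0.85 ± 0.18. Gzmb was not called with either (−0.41 ± 0.23, adjusted p = 0.347, and −0.61 ± 0.23, adjusted p = 0.0779). NK cytokines and chemokines fell in 12 of 19 and rose in 1 with PGE2 and fell in 13 with conditioned medium (13 and 1, and 13, over the list alone). Immediate early and NF-kB/NFAT targets fell in 14 and 13 of 24 and rose in 1 each, and ribosome biogenesis genes fell in 9 and 18 of 20. Camera called these 3 lists for both treatments, also with an estimated correlation.

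The difference between the effects in EP2KO and WT was tested directly. It called 0 genes for each treatment in each state with edgeR and 0 with DESeq2, with 272 genes (PGE2) and 346 (conditioned medium) at an unadjusted p under 0.05 in unstimulated cells and 465 and 266 in stimulated cells. The Ifng effect of PGE2 in stimulated cells differed by 0.89 ± 0.25 and that of Gzmb by 0.68 ± 0.32, and neither was called. In simulated data 35.8% of 2-fold differences between EP2KO and WT in the PGE2 effect on stimulated cells were recovered, so these counts do not show that the responses are equal.

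DKO cells showed little response. PGE2 called 0 genes without stimulation (184 at an unadjusted p under 0.05) and 0 with it (260), conditioned medium called 0 without stimulation (485) and 8 with it (723; n = 3 and 3 throughout), and DESeq2 called 0, 0, 0 and 24. With the replicate number as a block, PGE2 with stimulation called 2 genes and conditioned medium with stimulation 70, 44 higher and 26 lower, among them Nr4a1 (0.67, adjusted p = 0.0232; without the block 0.68 ± 0.22, adjusted p = 0.356). The 8 genes comprised 6 higher and 2 lower, among them the lipid gene Scd2 (1.34 ± 0.27), Vegfa (1.18 ± 0.23) and Arid5b (0.83 ± 0.17) among the rises and Serpina3g (−0.86 ± 0.18) and Tnfsf8 (−0.82 ± 0.18) as the falls. This count was 0 without the stimulated untreated replicate 2, 5 without its replicate 3, and 3 and 2 without conditioned medium replicates 2 and 3. Without the stimulated untreated replicate 2, the PGE2 count in stimulated cells was 3. With PGE2, Crem was 0.38 ± 0.22 higher without stimulation and 0.25 ± 0.22 with it, Ifng after stimulation was at 1724 CPM against 1669 untreated (0.05 ± 0.21), and none was called. Over the list alone, 9 of 24 cAMP-PKA-CREB targets rose with conditioned medium in stimulated cells. Camera called that list up in all 4 comparisons, with medians of 0.29 and 0.23 for PGE2 and 0.21 and 0.40 for conditioned medium without and with stimulation. With an estimated correlation the call held in stimulated cells (adjusted p = 0.0367 and 0.00133) and not in unstimulated cells (adjusted p = 0.0820 and 0.364 with an estimated correlation). Ribosome biogenesis genes were called down for conditioned medium with stimulation (median −0.31, camera adjusted p = 2.20e-10), also with an estimated correlation. With the replicate number as a block, camera also called 3 lists for PGE2 with stimulation: cytotoxicity up (adjusted p = 0.0786 without and 0.00591 with the block), cell cycle down (0.103 and 0.0318) and neutrophil markers down (0.164 and 0.00734). For conditioned medium with stimulation it also called oxidative phosphorylation (0.166 and 0.0445) and neutrophil markers (0.193 and 0.0264) down.

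The effects in DKO and EP2KO were compared directly. For PGE2 in stimulated cells they differed at 102 genes, 50 more positive and 52 more negative in DKO. More positive were Il2 (2.66 ± 0.50), Pou2f2 (1.89 ± 0.36), Tnf (1.81 ± 0.31), Ccl1 (1.73 ± 0.30), Cd69 (1.53 ± 0.20) and Ptger4 (1.07 ± 0.28, adjusted p = 0.0306). More negative were Dgat1 (−1.91 ± 0.37), Ifngr1 (−1.62 ± 0.22), Icos (−1.61 ± 0.25) and Crem (−1.31 ± 0.29). The difference for Ifng was 1.00 ± 0.27 with an adjusted p of 0.0501, and it was not called. Of the NK cytokines and chemokines 5 of 19 were more positive (12 over the list alone), of the immediate early and NF-kB/NFAT targets 8 of 24 (15 over the list alone), and of the cAMP-PKA-CREB targets 3 of 24 were more negative (6 over the list alone, with 1 more positive).

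For conditioned medium in stimulated cells 37 genes differed, 22 more positive in DKO and 15 more negative, among them Pdgfa (1.82 ± 0.24), Tnf (1.49 ± 0.31), Tnfsf14 (1.30 ± 0.26), Ifngr1 (−1.42 ± 0.22) and Crem (−1.20 ± 0.29). Without stimulation, 38 genes differed for PGE2 (13 more positive and 25 more negative; 96 with the replicate number as a block) and 23 for conditioned medium (6 and 17). Egr3 was more positive for both (1.53 ± 0.36 and 1.90 ± 0.38), and Crem (−1.80 ± 0.29, adjusted p = 2.92e-04, and −1.71 ± 0.29) and Dgat1 (−1.90 ± 0.34 for PGE2) were more negative. Ncr1 was more positive for PGE2 (1.06 ± 0.23). These counts moved when 1 library was left out. The count of 37 was 68 without DKO conditioned medium replicate 1, 67 without EP2KO untreated replicate 4, and 19 to 23 without EP2KO untreated replicate 1 or 2, EP2KO conditioned medium replicate 3, DKO untreated replicate 2, or DKO conditioned medium replicate 2 or 3. The count of 38 was 20 to 25 without EP2KO PGE2 replicate 3, DKO PGE2 replicate 1 or 3, or any 1 of the 3 DKO untreated libraries. The count of 23 was 9 to 15 without EP2KO untreated replicate 1 or 4, EP2KO conditioned medium replicate 3, DKO untreated replicate 2 or 3, or DKO conditioned medium replicate 1 or 3.

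**Figure D2:**
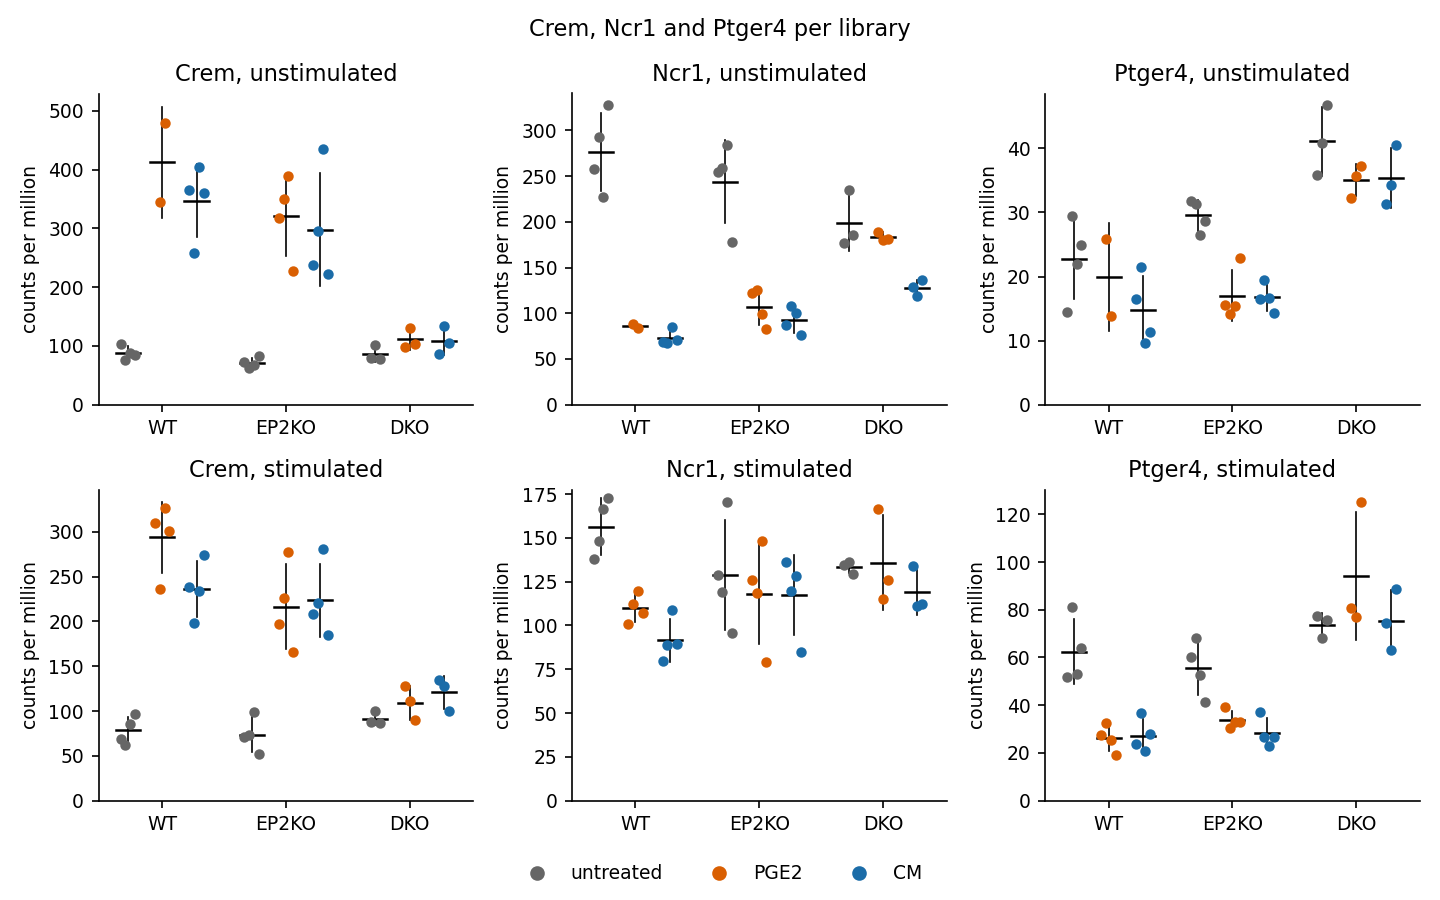
Each point is 1 library, with CPM of Crem, Ncr1 or Ptger4 on the vertical axis and genotype on the horizontal axis, unstimulated in the upper and stimulated in the lower panels; horizontal lines are group means, vertical lines span 1 SD either way, and CM is conditioned medium. Crem averaged 87.8 CPM in unstimulated untreated WT cells and 413 with PGE2, and Ncr1 averaged 276 and 85.8.

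A single score per library summarised these responses. The PGE2 signature, built from the genes called in WT, was higher without stimulation by 0.78 ± 0.05 with PGE2 and 0.79 ± 0.06 with conditioned medium in EP2KO (SE, n = 4 and 4; exact permutation p = 0.0286 for each, adjusted over 14 score comparisons 0.0571, treated above all untreated in 4 of 4). Paired by number, the first of these was 0.57 with the genes called under that block, and a sign-flip test of 4 pairs cannot give an exact p under 0.125. With stimulation it was higher by 0.52 ± 0.07 and 0.55 ± 0.07 (exact permutation p = 0.0286 for each, adjusted 0.0571, 4 of 4 for both). In DKO (n = 3 and 3, smallest possible p = 0.1) the differences were 0.12 ± 0.06 and 0.21 ± 0.06 without stimulation (exact permutation p = 0.2 and 0.1, adjusted 0.233 and 0.14; 2 of 3 and 3 of 3 treated libraries above all untreated) and 0.05 ± 0.02 and 0.18 ± 0.02 with it (exact permutation p = 0.2 and 0.1, adjusted 0.233 and 0.14; 2 of 3 and 3 of 3). Paired by number, the PGE2 differences in DKO were positive in 3 of 3 pairs in each state (0.01 to 0.23 without and 0.03 to 0.06 with stimulation), where 3 pairs cannot give an exact sign-flip p under 0.25. With the genes called under the block they averaged 0.08 (exact sign-flip p = 0.5) and 0.04 (0.25). The DKO values amount to 14.9% and 26.5% of those in EP2KO without stimulation and 8.85% and 32.3% with it, for PGE2 and conditioned medium. With 1 library left out, the PGE2 differences in DKO ranged from 0.07 to 0.17 without and 0.03 to 0.06 with stimulation. Those of conditioned medium in DKO ranged from 0.16 to 0.25 and 0.16 to 0.19. The difference between EP2KO and DKO had exact permutation p = 0.00245 for each treatment without stimulation and 0.0122 and 0.0163 with it.

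The activation score followed the anti-NK1.1 response. In WT it differed from untreated by −0.44 ± 0.03 with PGE2 and −0.44 ± 0.03 with conditioned medium, which is −48.3% and −48.4% of the effect of stimulation (n = 4 and 4, exact permutation p = 0.0286 for each, adjusted 0.0571, 4 of 4 below all untreated). Paired by number, the PGE2 value was −0.41, with the same lower limit on the exact p of 0.125. In EP2KO the changes were −0.27 ± 0.08 with PGE2 (exact permutation p = 0.0571, adjusted 0.1, 3 of 4 below) and −0.32 ± 0.08 with conditioned medium (exact permutation p = 0.0286, adjusted 0.0571), or −36.8% and −43.2%. In DKO they were −0.02 ± 0.08 and −0.08 ± 0.11 (exact permutation p = 0.9 and 0.7, adjusted 0.9 and 0.754), or −1.99% and −10.6%.

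**Figure D3:**
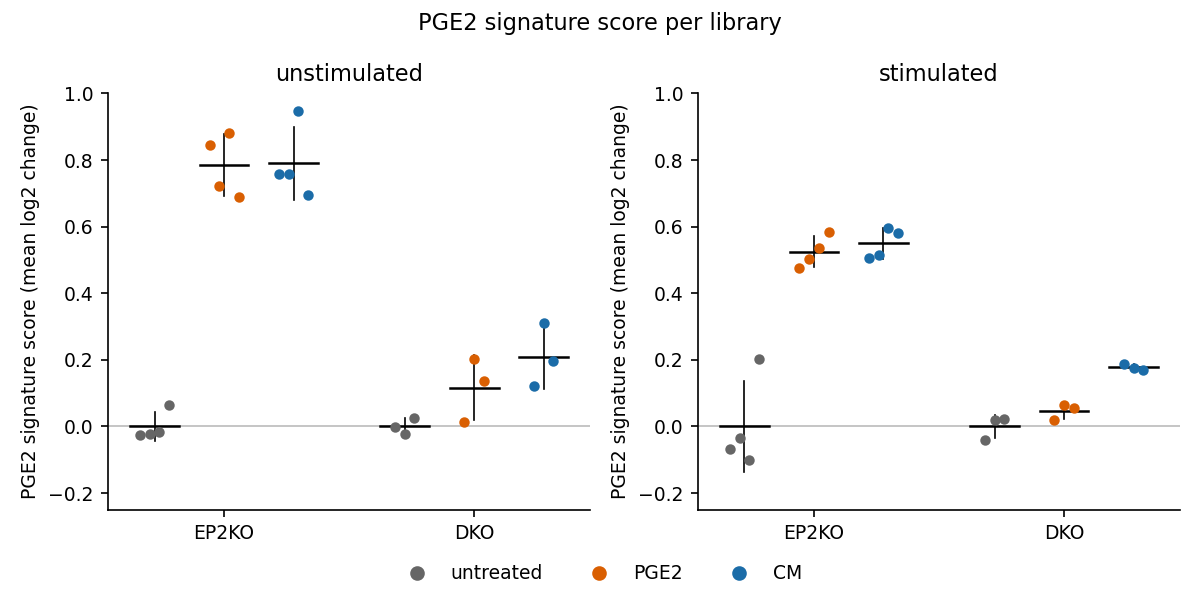
Each point is the PGE2 signature score of 1 library, a mean log2 change against the untreated mean of its genotype and state, for EP2KO and DKO; horizontal lines are group means, vertical lines span 1 SD either way, and CM is conditioned medium. EP2KO scores averaged 0.78 with PGE2 in unstimulated cells and 0.52 in stimulated cells, against 0.12 and 0.05 in DKO.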

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

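In this part, the tests of passing counts and of X-linked homologs, of an even admixture, and of a fraction of cells with EP4 were chosen only after the results were seen. Over 122 tests, each of 1 measure in 1 group of 4 libraries, 6 values of 5 libraries lay apart from the rest of their group, and chance gives about 1 in 20. These were the total of untreated unstimulated EP2KO replicate 4 (1020000 counts, nearest 1202000) and its PGE2 signature score (0.0638, nearest −0.0162), Ptger4 in unstimulated EP2KO replicate 4 with PGE2 (22.9 CPM, nearest 15.6), Ptger2 in stimulated EP2KO replicate 4 with PGE2 (12.6 CPM, nearest 6.51), Xcl1 in unstimulated EP2KO replicate 1 with conditioned medium (2275 CPM, nearest 1935), and the activation score of untreated stimulated EP2KO replicate 4 (−0.20, nearest 0.04).

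Treatment effects differed between groups in 6 comparisons. In WT, the PGE2 effect differed with stimulation at 140 genes, which was not tested by splits because 1 group has 2 libraries, and the conditioned medium effect at 235. Of 100 splits of the conditioned medium and untreated WT libraries within each state, 7 gave 235 or more genes, and the highest other gave 1007. Such counts point to a structure of the samples: the treated and untreated libraries differ in both states, and exchanging labels mostly in 1 state adds these effects in place of subtracting them. For this interaction the splits therefore do not measure chance, and whether chance can be excluded was not decided. Between DKO and EP2KO, the PGE2 effect differed at 38 genes without stimulation (2 of 100 splits as high, highest other 49) and at 102 with it (1 of 100, highest other 79). For these differences genotype labels were exchanged within each treatment. The conditioned medium effect differed at 23 genes without stimulation (3 of 100, highest other 49) and at 37 with it (6 of 100, highest other 264). For the first 3 of these counts the share is under 0.05, without adjustment over the comparisons. For the 38 and the 23, another split gave more genes than the real labels, so chance is not excluded. The exchanges also ignored replicate numbers, although the comparison with 38 genes was taken as paired. Nor can chance be excluded for the 37. There a split with several times as many genes again points to a structure of the stimulated samples, whose source was not tested.

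For each of the following, only the real one of the 35 splits of 8 libraries gave as many genes (1 of 35). That is the smallest share this design allows, under 0.05 without adjustment over the comparisons. Anti-NK1.1 called 4508 genes in WT and 3575 in EP2KO, against 1826 and 1800 in the highest other split. PGE2 in EP2KO called 338 without stimulation, against 29, and 782 with it, against 400, and in stimulated WT 1676, against 1417. Of these, PGE2 in unstimulated EP2KO and in stimulated WT was taken as paired. The 7 other splits that part every pair are too few for a share under 0.05, so chance is not excluded there. Conditioned medium without stimulation called 883 in WT and 469 in EP2KO, against 37 and 17, and with stimulation 1654 and 1117, against 1070 and 457. Chance cannot be excluded for conditioned medium against PGE2 in stimulated WT, where 2 of 35 splits gave 1 gene or more and the highest other gave 1. For the untreated genotypes the real split again gave the most, with 7 genes between EP2KO and WT, against 2 in the highest other split (1 of 35). Between DKO and EP2KO it gave 6, against 5 (1 of 35). The EP2KO minus WT differences called 0 genes with edgeR and with DESeq2 in the tested cases (346 at an unadjusted p under 0.05 for conditioned medium without stimulation, 465 and 266 for PGE2 and conditioned medium with it), so all 100 splits gave as many for conditioned medium without stimulation (highest other 1) and for PGE2 and conditioned medium with stimulation. The highest other split gave 292 and 556 genes in the latter 2 cases, which points to a structure of the stimulated samples, whose source was not tested. In DKO, the 10 splits of 6 libraries are too few to give a share under 0.05. Anti-NK1.1 called 3242 genes there, against 2 in the highest other split (1 of 10 splits as high). PGE2 called 0 without and 0 with stimulation, against 1 and 0 (10 of 10 each), and conditioned medium 0 and 8, against 0 and 2 (10 of 10 and 1 of 10). Where replicate numbers pair the samples, the splits that also part every pair gave no more genes than these: 10 for PGE2 in unstimulated EP2KO and 234 in stimulated WT (7 splits each), where the 27 that part fewer pairs reached 29 and 1417. In DKO, the 3 such splits reached 2 for anti-NK1.1, 1 and 0 for PGE2 without and with stimulation and 0 for conditioned medium with it, and the 6 that part fewer pairs 1, 1, 0 and 2. DESeq2 also called 0 in the 3 cases of 0, and edgeR 184, 260 and 485 at an unadjusted p under 0.05.

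Each library carried some transcripts of the other sex: Xist in DKO stood at 8.88% of its mean over all 64 libraries, and in WT and EP2KO Uty, Kdm5d, Ddx3y and Eif2s3y stood at 6.86%, 8.36%, 10.1% and 13.3% of theirs. Reads of X-linked homologs counted on the Y-linked genes do not account for Xist, whose lowest count in a DKO library was 43. Counts passing between pooled libraries could account for both, since the share of Xist lay within the range of the 4 Y-linked genes. Cells of the other sex in the cultures also stay open, because Xist in DKO followed the replicate number within groups (permutation p = 0.00225). No other biological explanation was tested. If counts did pass between libraries, the fold changes given here may be compressed, and a low level in a knockout may come partly from other libraries.

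PGE2 signature scores were smaller in EP2KO than in WT, at 71.6% without and 61.1% with stimulation for PGE2, but the genes were chosen in WT. The outlying untreated stimulated EP2KO replicate 4 does not explain all of this: without it, and with genes chosen in unstimulated EP2KO, the stimulated WT score was still 132% of that in EP2KO (difference of 5.26 SE). Loss of EP2 is a candidate explanation, since with the latter genes and all libraries the stimulated score was 140% of that in EP2KO (two-sided exact permutation p = 0.0188). With those genes the unstimulated score was 99.9% of that in EP2KO, from 2 libraries of WT with PGE2, and conditioned medium gave 122% with stimulation (exact permutation p = 0.0767), 116% without the outlying library (p = 0.175) and 97.6% unstimulated (p = 0.836). With PGE2 unstimulated, genes chosen in stimulated WT gave 103.5% (exact permutation p = 0.859) and in stimulated EP2KO 97.69% (exact permutation p = 0.9105). So that gap appeared only with genes chosen on the scored WT libraries. With stimulation, genes chosen in unstimulated WT gave 143.8% (exact permutation p = 0.0269), and without the outlying library 139.7% (exact permutation p = 0.0555). This and the 140% argue against choice on the scored libraries as the whole stimulated PGE2 gap. Its size stays open, because with genes chosen in stimulated EP2KO the stimulated score was 110% of that in EP2KO (exact permutation p = 0.467). Without the outlying library it was 103% (exact permutation p = 0.817; conditioned medium 100%, p = 1), and that choice favours EP2KO.

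DKO libraries kept small signature scores, with means over both states of 0.08 for PGE2 and 0.19 for conditioned medium (exact permutation p = 0.025 and 0.005 over 400 relabellings within states, the latter the smallest they allow). These relabellings ignore the replicate numbers, which were taken to pair PGE2 in both states and conditioned medium with stimulation. Within 1 state, 3 pairs cannot give an exact sign-flip p under 0.25. If a number marks the same sample in both states, that limit holds over both states too. The p-values of the relabellings would then overstate the evidence. Counts passing from the pool as the same share of every library would raise treated and untreated libraries alike. By themselves they could not give a score above 0. An equal number of passed counts would weigh more in shallower libraries, and depth differed between the DKO groups, which was not tested. The conditioned medium score with stimulation lay 8.5 SE above 0, from 3 libraries against 3 (exact permutation p = 0.1). Counts passing unevenly were not tested. A fraction of cells that kept EP4 is a candidate explanation for the PGE2 part: with genes chosen in unstimulated EP2KO, DKO scores were 14.5% ± 6.63 (SE) and 15.6% ± 3.24 of those in EP2KO without and with stimulation, a difference of 1.13 percentage points, while genes chosen in stimulated EP2KO gave 20.5% and 11.4% (difference of 0.897 SE) and genes chosen in stimulated WT 18.4% and 8.85% (0.867 SE), so with SEs this wide equal shares are allowed but not shown. In DKO, conditioned medium exceeded PGE2 by 0.11 (exact permutation p = 0.025, again without regard to the numbers). A fraction of cells with EP4 would not explain this if it answered both treatments alike, which was assumed and not tested. In EP2KO the scores of PGE2 and conditioned medium were 0.78 and 0.79 without and 0.52 and 0.55 with stimulation. Other components of the conditioned medium stay open, since its difference from PGE2 correlated between stimulated DKO and EP2KO across genes, which are not replicates, at r = 0.147, and 14.6% of 1400 relabelled pairs reached that value.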

How the results depend on the processing

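Of the settings below, the conditioned medium libraries numbered 2 and 4 alone and the EP2KO libraries numbered 1 to 3 alone were chosen after seeing the data. In this part scores are judged by the unadjusted exact p, since the lowest adjusted value of the 14 score differences was 0.0571. No score difference with an unadjusted exact p under 0.05 turned its direction in the settings run for scores. Nor did a called named gene in the settings run for named genes, which did not include leaving out a library. Below the threshold, the activation score in DKO changed sign with 1 library left out: with PGE2 from −0.02 to 0.05 without its replicate 1 and to about 0 without untreated replicate 3, and with conditioned medium from −0.08 to 0.02 without its replicate 1. So did 3 named-gene values near 0 (1 with DESeq2, 1 with size factors and 3 without a filter). Across the 29 comparisons, the count of called genes stayed within 1.5 times its value for 24 with DESeq2, 28 with DESeq2 size factors within edgeR and 22 of 29 without a filter on low counts. It did so for 237 of 285 fits with 1 library left out. All 14 score differences kept their side of an unadjusted exact p of 0.05 in the first 3 of these settings. So did 95 of 100 with 1 library left out (4 lost and 1 gained an unadjusted exact p under 0.05). Of the named genes, 1099 of 1107 values kept their call with DESeq2 (4 lost, 4 gained), 1126 of 1130 with size factors (2 lost, 2 gained) and 1053 of 1130 without a filter (70 lost, 7 gained). Depth limits genes of a few CPM, such as Ptger2, and a called fold of a gene near 1 count per library rests on few molecules or reads.

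DESeq2 called 24 genes for conditioned medium in stimulated DKO cells, 0 between conditioned medium and PGE2 in stimulated WT, 369 for the interaction of conditioned medium with stimulation, and 39 and 65 for the DKO minus EP2KO difference of conditioned medium without and with stimulation. DESeq2 size factors called 0 between conditioned medium and PGE2 in stimulated WT. Without a filter, PGE2 and conditioned medium in stimulated cells called 520 and 742 genes in EP2KO and 4 and 21 in DKO, conditioned medium against PGE2 in stimulated WT called 2, its interaction with stimulation 139, and DKO against EP2KO 15. Camera with an estimated correlation called 56 of the list tests in place of 100. With the untreated libraries split 2 and 2, so that fewer libraries stood behind each comparison, a mean of 128.3 genes without and 592.2 with stimulation were called for both treatments in WT. Conditioned medium in unstimulated WT called 328 genes with its libraries 2 and 4 alone, again with fewer samples. With EP2KO libraries 1 to 3 alone, the DKO minus EP2KO difference of conditioned medium in stimulated cells called 64 genes, and the other 7 counts stayed within 1.5 times. Where no cause is given, the cause was not tested.

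Leaving out 1 library moved the counts below by more than 1.5 times at least once. PGE2 without stimulation ranged from 129 to 321 genes in WT and 222 to 299 in EP2KO, and conditioned medium from 483 to 868 in WT and 304 to 406 in EP2KO. With stimulation, PGE2 in DKO ranged from 0 to 3, conditioned medium in DKO from 0 to 10, and conditioned medium against PGE2 in WT from 0 to 3. The interactions with stimulation ranged from 33 to 154 for PGE2 and 136 to 362 for conditioned medium. The DKO minus EP2KO differences ranged from 20 to 41 (PGE2 without stimulation), 9 to 27 (conditioned medium without) and 19 to 68 (conditioned medium with stimulation). EP2KO against WT ranged from 4 to 7 and DKO against EP2KO from 6 to 10. In EP2KO the activation score difference ranged from −0.34 to −0.24 with PGE2 and −0.39 to −0.29 with conditioned medium, and with 3 libraries against 4 the exact test has fewer relabellings.

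The replicate number was also fitted as a block within each genotype, for 27 comparisons. In the 8 where the numbers were taken to pair the samples, the block moved 4 counts by more than 1.5 times and called 3 more named genes and 5 more lists. It left 2 scores unable to reach an unadjusted exact p under 0.05, and changed no other call. Over all groups, deviations of same-numbered libraries from their group means correlated above 0.1 in 38 of 50 pairs in WT, 47 of 60 in EP2KO and 38 of 45 in DKO (lowest −0.12, −0.0675 and 0.0234). In the other 19 comparisons not every pair did or there were only 2, so the numbers were not taken to pair the libraries there. As a hint from the data, each library's correlations with the other groups of its genotype were averaged per number. The mean was highest for its own number in 16 of 22, 18 of 24 and 17 of 18 libraries. The neutrophil gene S100a8, chosen after its values were seen, followed the number (permutation p = 1e-05, the smallest that 1e+05 resamples can give). It was highest in number 2 of WT (mean 95.1 CPM), 1 of EP2KO (240.7 CPM) and 2 of DKO (34.9 CPM) in all 6 groups of each genotype. Erythroid markers took 0.0035% to 0.0101% of the counts in the EP2KO libraries numbered 4 and at most 0.00104% in every other library. Comparisons taken as paired and as not paired also share untreated libraries, as do PGE2 and conditioned medium in stimulated WT. The number may therefore mark a shared sample in the other 19 comparisons too, and their counts without the block leave that out. With the block, 9 of 27 counts stayed within 1.5 times and 18 rose past it. PGE2 without stimulation called 679 genes in WT and 646 in EP2KO, and conditioned medium 1755, 833 and 9 in WT, EP2KO and DKO. With stimulation, PGE2 called 1254 in EP2KO and 2 in DKO, and conditioned medium 1713 and 70. Conditioned medium against PGE2 called 1 without and 24 with stimulation. The interactions with stimulation called 367 and 919, the DKO minus EP2KO differences 96 and 70 without and 259 and 169 with stimulation for PGE2 and conditioned medium, and the EP2KO minus WT difference of PGE2 with stimulation 3. Under this block a sign-flip test of 4 numbers cannot give an exact p under 0.125. So 7 score differences with an unadjusted exact p under 0.05 could not keep it, 2 of them paired: 0.57, 0.60, 0.46 and 0.49 for the signature in EP2KO (PGE2 and conditioned medium without, then with stimulation), and −0.41, −0.41 and −0.29 for the activation score (WT with PGE2, WT with conditioned medium, EP2KO with conditioned medium). All 1103 named-gene values kept their direction, and 19 gained a call (16 of them not paired).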

Other observations

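In this part, the choice of the genes named between untreated EP2KO and WT and of the window around Ptger2 was made after the called genes were seen. Homing, receptor and transcription factor genes also responded in stimulated EP2KO cells. The lymph node homing gene Ccr7 rose by 3.52 ± 0.52 with PGE2 and 3.17 ± 0.54 with conditioned medium, the chemokine receptor gene Ccr2 by 1.09 ± 0.15 and 1.04 ± 0.15, and the retention molecule gene Cd69 changed by −1.55 ± 0.13 and −1.19 ± 0.13 (log2 ± SE, n = 4 and 4). Of 19 trafficking and adhesion genes 5 rose with each treatment, with 2 and 1 lower (camera adjusted p = 0.103 for PGE2 and 0.0305 for conditioned medium, the latter at adjusted p = 0.154 with an estimated correlation). Of 20 cytokine receptors 3 and 5 rose and 1 fell in each case (camera adjusted p = 8.17e-04 and 0.00692, adjusted p = 0.0367 and 0.0925 with an estimated correlation). Ifngr1 rose by 1.95 ± 0.15 and 1.84 ± 0.15, and Il12rb2, which encodes a chain of the IL-12 receptor, by 1.02 ± 0.17 and 0.88 ± 0.17, while Il2ra, the IL-2 receptor alpha chain gene, changed by −1.08 ± 0.19 and −1.19 ± 0.19. NK transcription factors rose in 7 and 6 of 18, with 2 lower in each case (camera adjusted p = 0.00321 and 0.0188, adjusted p = 0.234 and 0.398 with an estimated correlation), among them Tcf7 (1.01 ± 0.16 and 0.98 ± 0.16) and Runx3 (0.64 ± 0.15 and 0.75 ± 0.15). The inhibitory receptor gene Tigit rose by 1.89 ± 0.45 with each, and the inhibitory receptor gene Havcr2 changed by −1.07 ± 0.19 and −1.29 ± 0.19.

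The genes called in WT and EP2KO overlapped. For PGE2, both genotypes called 129 genes higher and 65 lower without stimulation, against 3.59 and 1.58 for independent lists, and 280 higher and 354 lower with stimulation, against 21.8 and 40.3, with none in opposite directions. Of the genes called for PGE2 in WT, 97.8% without and 97.3% with stimulation had the same sign in EP2KO. For anti-NK1.1, WT and EP2KO shared 1690 higher and 1219 lower genes, with 1 in opposite directions, and WT and DKO shared 1551 and 1133. These comparisons share no libraries. In WT, PGE2 without and with stimulation called 151 genes higher and 71 lower in both states and 2 in opposite directions.

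Of the 7 genes that differed between untreated unstimulated EP2KO and WT, 3 lie on chromosome 14 near Ptger2: Rpph1 (50807449 to 50807767, 5.80 Mb away), Gm26782 (50870324 to 50880603, 5.87 Mb) and Rpgrip1 (7.11 Mb), changed by −2.51 ± 0.46, −1.53 ± 0.31 and −2.00 ± 0.28. The other 4 are Wdfy1, Tnfrsf11b (2.04 ± 0.40), Gm8276 (2.89 ± 0.48) and Rprl3. In untreated unstimulated cells Rprl3 was at 0 CPM in all WT libraries and at a mean of 11.1 CPM in EP2KO. Rpph1 and Rprl3 are copies of the RNase P RNA and Gm26782 is an antisense gene, so their counts are uncertain. Of the tested genes, 75 lie within 10 Mb of Ptger2. A hypothesis is that DNA of another mouse strain kept around the targeted gene may account for them, which would also shift genes nearby that were not called. Of those, with Ptger2 itself left out, 7 of 71 (9.86%) had an unadjusted p under 0.05, against 744 of 10500 (7.09%) elsewhere (Fisher's exact p = 0.35), so the test did not decide, and calls of single genes near Ptger2 in EP2KO and DKO carry that limit.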
